A study of Mus musculus with 12 samples.

How the data were processed

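RNA from the neocortex and hippocampus of mouse embryos was measured on 12 one-colour CodeLink whole-genome arrays, on which biotin-labelled RNA is stained with streptavidin-Cy5. Per the labels, 8 arrays belong to a Nestin experiment at stage E18.5, with 4 control and 4 mutant animals taken as littermates from 2 litters. The other 4 belong to a separate NEX experiment at stage E14.5, with 2 control and 2 mutant littermates. Sip1, the deleted gene, has the current symbol Zeb2. Groups were taken from the sample titles.

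Spot intensity and local background intensity were measured with CodeLink Expression Analysis version 4.1, per the file headers, and the scanner files were deposited without further steps being recorded. The authors' deposited value table holds log2 values. Set against each array's own background-subtracted scanner intensity, its columns gave a Pearson correlation across spots above background of at least 0.999872. Its column medians were 6.54 on all 12 arrays, its empty cells were exactly the spots whose quality flag was neither good nor near background (218 to 625 per array), and no column was of a sample outside the 12. The scale is therefore log2, with no centring per gene; the exact scaling step is not given in the sources used here.

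For the results below, the background was corrected with limma's normexp method (offset 50) on the spot mean and the local background median, control spots were then left out, and log2 values were quantile normalized over all 12 arrays. Spots flagged as neither good nor near background were set to missing. Of 34967 probes, 31380 were flagged above background on at least 2 arrays and were kept. The given probe table names 1 gene symbol for 21615 probes and several for 681, and 12671 probes are unnamed here. One probe per symbol was kept, the one with the highest mean over the arrays, and each unnamed probe stayed on its own, which left 28252 features, 16739 of them named genes. Ntf3, which was to be named in every comparison, is not analysed here because no named probe carries it.

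A linear model with the 4 groups and a litter term for the Nestin arrays was fitted to all 12 arrays with limma version 3.58.1 in R version 4.3.3 (lmFit and eBayes). Benjamini-Hochberg adjusted p under 0.05 counted as changed. Every adjusted p for a gene comes from this model, unless another setting is named. Values of a second probe of a gene come from the same model fitted to all 31380 kept probes. Standard errors (SE) are the model's moderated ones. The comparisons were mutant minus control in each experiment, the NEX difference minus the Nestin difference, and Nestin control minus NEX control. The litter block comes from the design, and the litter deviations of control and mutant arrays correlated at 0.887 across features. A set of 32 gene lists, written before the data were examined, was tested with limma's camera at a preset correlation of 0.01. Each list was tested again with a correlation estimated per list and with fry. These tests were planned for the first 3 comparisons and were run on the last one too. The labels describe separate animals, so the spread between arrays includes that between animals.

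The genes named in the text follow a rule also set before the data were examined. Zeb2, Fgf9 and Sfrp1 are always given. In each experiment up to 12 genes with the largest rise and up to 12 with the largest fall are named among those past the threshold whose mutant arrays all lay on one side of all control arrays after removal of litter means, leaving out unnamed probes and symbols of provisional genes. Up to 4 members of a list with the smallest p, and up to 6 genes per sign for the difference between experiments, complete the set.

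The fit was tested on simulated arrays of 26342 features, 50 of them changed at each of several folds. For the Nestin comparison 88% of features changed 1.5-fold and 98% of features changed 2-fold were recovered. For the NEX comparison the shares were 46% and 96%. Of the simulated calls, 15 of 207 in Nestin and 14 of 184 in NEX fell on unchanged features. The simulated noise was independent between features and kept only litter and stage, so these shares may not hold for the real arrays. The number of arrays limits the precision. Between 74.7% and 84.3% of probes were above background per array, and the median local background was 82 to 120 intensity units. Alternatives covered the background correction, normalization, source of values, filter on dim probes, litter and lot terms, replicate numbers, probes per gene, variance model, array weights and leaving out each array. The array lot was inferred from the start of each array's identifier, as the labels used here do not name it.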

Results

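Gene expression was measured in the neocortex and hippocampus of mouse embryos in which Sip1 (Zeb2), a zinc finger transcription factor, was deleted conditionally. In the Nestin experiment, named after a Cre driver active in neural progenitors, 4 arrays labelled control and 4 labelled mutant came from 2 litters at embryonic stage E18.5. In the NEX experiment, named after a driver active in postmitotic cortical neurons, 2 arrays of each label came from E14.5. Median spot intensity per array ranged from 165 to 226 units over a local background of 82 to 120. Arrays of one label and litter correlated across features at 0.987 to 0.997 in the Nestin experiment, and Nestin arrays of different litters at 0.953 to 0.965. Bacterial control transcripts averaged 5.09 on the log2 scale on litter 1 arrays, 8.31 on litter 2 and 9.01 on NEX arrays.

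The targeted gene was examined first. Zeb2 was not lower on the Nestin arrays labelled mutant. Its probe with the highest signal read 2.02-fold higher there than on the arrays labelled control (log2 difference 1.02 ± 0.25 SE, n = 4 per label, limma adjusted p = 0.0519), just short of the threshold, which it passed when any NEX array was left out (adjusted p = 0.0197 to 0.0344). The difference was 0.75 within litter 1 and 1.28 within litter 2. A second Zeb2 probe, in the fit to all kept probes, gave 0.53 ± 0.17 (limma adjusted p = 0.129). Between the controls of both experiments the probes went opposite ways (Nestin minus NEX 0.96 ± 0.31 for the first, -0.75 ± 0.20 for the second). On Nestin controls the first read 10.2 to 10.5 in litter 1 and 8.20 to 8.53 in litter 2. The second read 6.60 to 6.62 and 7.07 to 7.11. The probes are therefore not interchangeable measures of Zeb2. In the NEX experiment the first probe gave 0.22 ± 0.36 and the second -0.06 ± 0.23 (n = 2 per label, limma adjusted p = 1.00 for both). Where these probes lie relative to the deleted part of the gene is not given in the sources used here, and a probe outside it would not check the labels. Because the measured direction goes against the label, groups are called by their labels throughout, and every direction below is that of the arrays labelled mutant against those labelled control.

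**Figure D1:**
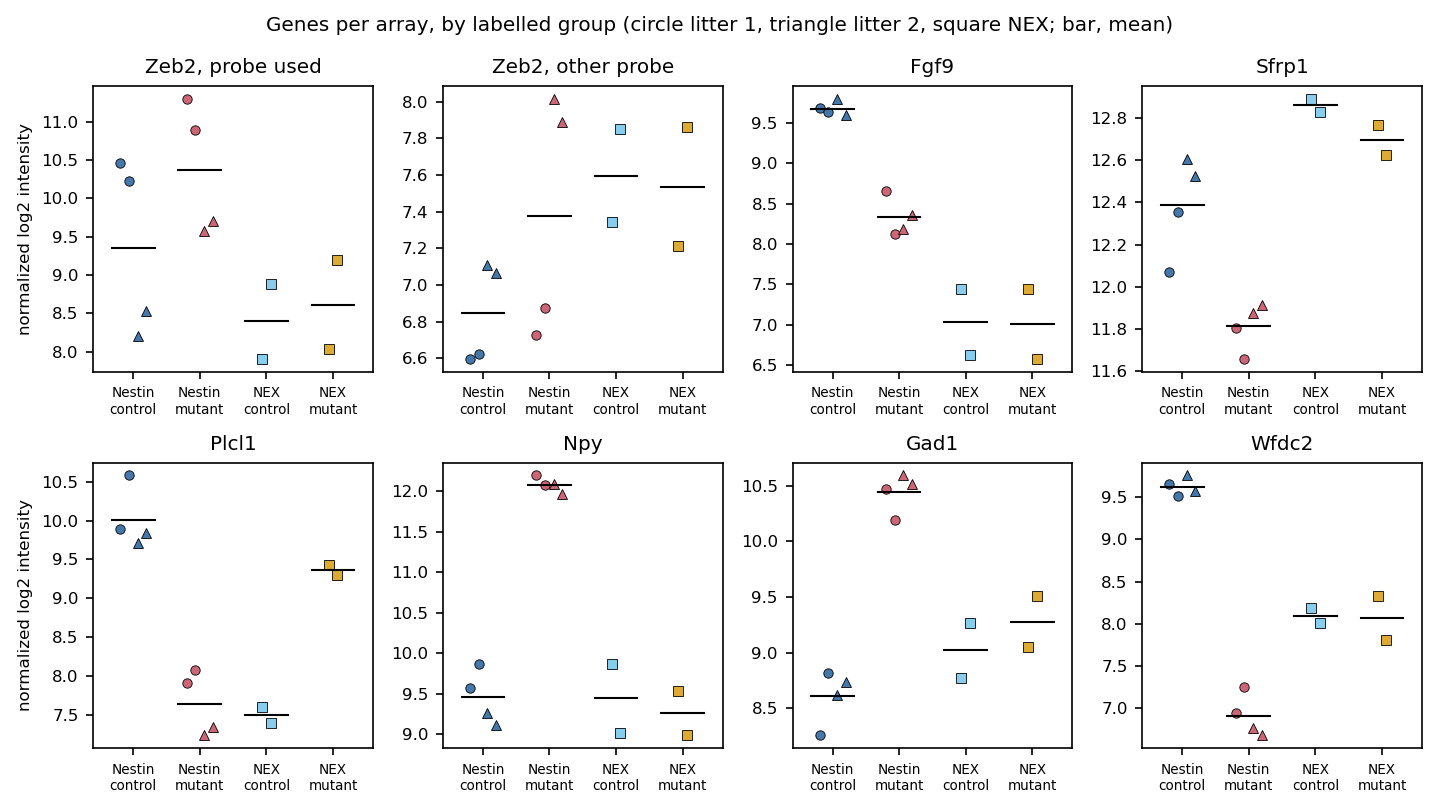
Normalized log2 intensity of both Zeb2 probes and 6 genes on each of the 12 arrays (vertical axes) by labelled group (horizontal axes); circles are Nestin litter 1, triangles Nestin litter 2, squares NEX, and bars group means. The probe used for Zeb2 lies higher on the Nestin arrays labelled mutant by 1.02 on the log2 scale, and Plcl1 differs by -2.37 in Nestin and 1.87 in NEX.

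The Nestin comparison asked how gene expression differs when Sip1 is removed from cortical progenitors and their progeny. Genes of cortical inhibitory interneurons were higher on the arrays labelled mutant. Npy, a neuropeptide of these cells, was 6.18-fold higher (log2 difference 2.63 ± 0.18 SE, limma adjusted p = 1.44e-05, n = 4 per label), and Sst, which encodes somatostatin, was 4.71-fold higher (2.24 ± 0.32). Gad1, the enzyme that makes the inhibitory transmitter GABA, rose 3.57-fold (1.84 ± 0.15), and Lhx6, a transcription factor of interneurons born in the medial ganglionic eminence, rose 3.74-fold (1.90 ± 0.25). Of 22 measured interneuron genes, 14 rose, none fell and 8 did not pass the test, and 15 rose when adjusted over the list alone. The list's median log2 difference was 0.80 (camera adjusted p = 3.14e-21, and adjusted p = 0.00132 with an estimated correlation), with 0.75 within litter 1 and 0.81 within litter 2.

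Other genes with the largest rises were Npas1, Pnoc (4.21-fold), Calb1 (4.20-fold), Rpp25 (3.73-fold), Cacng3 (3.52-fold), Rpp21 (3.45-fold), Nrxn3 (2.92-fold) and Tac2 (2.91-fold). Pnoc and Tac2 encode neuropeptide precursors and Calb1 a calcium-binding protein. Among the falls, Wfdc2, a secreted protein with a whey acidic protein domain, was lower by the widest margin (log2 difference -2.71 ± 0.13, 6.56-fold), followed by Plcl1, a phospholipase C-like protein (-2.37 ± 0.13, 5.16-fold). Ap1m2, an adaptor subunit of epithelial cells, was 4.99-fold lower, Grb7 3.87-fold, Tuba4a 3.69-fold, Dmrta1 3.35-fold and Tmem229a 3.30-fold. Ackr4, the cell cycle inhibitor Cdkn1a (2.81-fold), Kdf1 (2.69-fold), Slc27a2 (2.67-fold) and Mgat4c (2.63-fold) completed the set. Ap1m2 lost its call without any single Nestin array (adjusted p = 0.0548 to 0.0741), and Tuba4a without control 2.1 (0.0523) or mutant 2.2 (0.0524). Ackr4 was above background on 1 of the 4 arrays labelled mutant, and Npas1 on 2 of the 4 labelled control, so no fold is given for either; over the settings tried their log2 differences ran from -3.48 to -1.12 and from 1.62 to 4.28. With plain background subtraction those of Lhx6, Tac2 and Kdf1 were 3.51, 2.67 and -2.29, and with the mean of its probes that of Calb1 was 1.199.

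Fgf9 and Sfrp1, named before the data were examined, were both lower. Fgf9, a growth factor made by cortical neurons, was 2.54-fold lower on the arrays labelled mutant (log2 difference -1.34 ± 0.20, limma adjusted p = 0.00289, n = 4 per label), and its other probe gave -0.76 ± 0.08. Sfrp1, a secreted Wnt antagonist, was 1.49-fold lower (-0.57 ± 0.08, adjusted p = 0.00218). Fgf9 was the 1 member of 14 measured FGF and neurotrophin ligands to pass the test, over all genes and adjusted over the list alone.

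Astroglial genes fell together. Of 27 measured, 9 fell, none rose and 18 did not pass, and 12 fell when adjusted over the list alone (median -0.28, camera adjusted p = 4.06e-09, and adjusted p = 0.0297 with an estimated correlation). Acsbg1 (log2 difference -1.09 ± 0.10), the glycolytic enzyme Aldoc (-1.02 ± 0.09), the matrix protein Bcan (-0.72 ± 0.11) and Atp1b2 (-0.49 ± 0.08) were among them. Radial glia genes, those of the cortical stem cells, fell with 2 of 24 past the test over all genes and 10 adjusted over the list alone (median -0.23, adjusted p = 0.0297 with an estimated correlation). The 2 were Dmrta1 and Sox3 (-0.81 ± 0.13). Microglial genes also fell, 6 of 16 over all genes and 8 adjusted over the list alone, where 1 rose (median -0.29, adjusted p = 0.0407 with an estimated correlation). C1qb (-0.82 ± 0.10), Tyrobp (-0.77 ± 0.11), Fcer1g (-0.67 ± 0.08) and C1qa (-0.66 ± 0.07) led this group.

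A further 7 lists were lower with the preset correlation but not with an estimated one. These were cell cycle (1 of 28 fell, adjusted p = 0.122 with an estimated correlation), Notch pathway (3 of 21, adjusted p = 0.106), TGF-beta and BMP pathway (2 of 32 fell and 1 rose, adjusted p = 0.106), immediate early genes (4 of 20, adjusted p = 0.239), epithelial genes that ZEB factors repress in other tissues (3 of 23, adjusted p = 0.378), ERK feedback genes (3 of 13, adjusted p = 0.445) and meninges (1 of 16, adjusted p = 0.494). By fry, immediate early genes (adjusted p = 0.00935), Notch pathway (0.0143), cell cycle (0.0184), TGF-beta and BMP pathway (0.0338) and the epithelial genes (0.0428) passed. ERK feedback genes did not (fry adjusted p = 0.107). Adjusted over the list alone, 10 cell cycle genes fell. The 3 epithelial genes that fell over all genes were Ap1m2, the adhesion molecule Epcam (-1.08 ± 0.15) and the polarity gene Crb3 (-0.72 ± 0.08). Notch1 (-0.54 ± 0.08), Nrarp (-0.54 ± 0.09) and Hey1 (-0.52 ± 0.11) fell in the Notch list, and the ERK feedback genes Etv4 (-0.68 ± 0.15), Spry2 (-0.50 ± 0.11) and Spry1 (-0.46 ± 0.10) fell in theirs. Hey1, Etv4, Spry1 and Spry2 lost their calls without Nestin control 1.1 (adjusted p = 0.0628, 0.0648, 0.0668 and 0.0571) and without several other single arrays.

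The remaining 21 lists did not pass camera in Nestin; by fry, 2 of them did, apoptosis (adjusted p = 0.0256) and FGF and neurotrophin ligands (0.0428). Ganglionic eminence and striatum genes had 1 of 18 higher and 1 lower, and 5 higher and 1 lower adjusted over the list alone (median 0.12, camera adjusted p = 0.0866), apoptosis genes 3 of 20 lower (0.0711), endothelial genes 1 of 18 lower (0.0785) and intermediate progenitor genes 1 of 16 lower (0.197). FGF and neurotrophin ligands (adjusted p = 0.213), oligodendrocyte lineage (0.266), thalamus (0.266), upper-layer neurons (0.267), synapse (0.282), Wnt pathway (0.349), pericytes (0.349), Cajal-Retzius cells (0.382), gp130 signalling (0.431), hypoxia (0.438), hippocampus and cortical hem (0.455) and erythroid genes (0.465) were further from it. So were deep-layer neurons (0.571), Wnt antagonists (0.571), choroid plexus (0.701), sex-linked genes (0.795) and axon guidance (0.971). The median and the test differed in sign for upper-layer neurons, Wnt antagonists and axon guidance.

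Over all 28248 features tested, 314 were higher and 595 lower on the Nestin arrays labelled mutant, and at least 1.5-fold 124 were higher and 215 lower. Without the litter block the counts were 68 and 110. For the difference within litter 1, 904 features passed, 459 of them among the 909. Within litter 2, 189 passed, 177 of them among the 909. Both came from a fit to all arrays with a shared spread. Arrays of one label correlated at 0.987 and 0.989 in litter 1 and at 0.996 and 0.997 in litter 2. A shared spread can raise the first count and lower the second, so they do not compare the breadth of the effect between litters. Leaving out control 2.1, control 2.2, mutant 2.1 or mutant 2.2 lowered the count of 909 to 530, 575, 543 and 538.

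**Figure D2:**
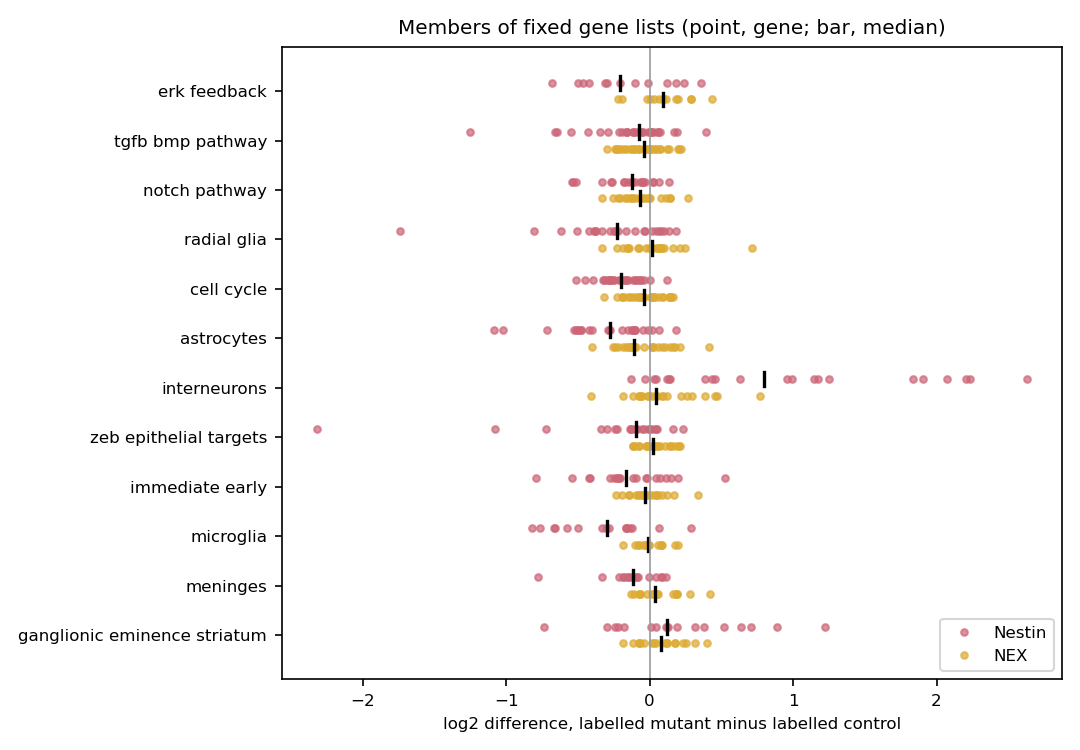
Log2 difference, labelled mutant minus labelled control (horizontal axis), of each measured member of 12 fixed gene lists (vertical axis) in the Nestin and NEX comparisons; points are genes and bars are list medians. The interneuron median is 0.80 in Nestin and 0.05 in NEX.

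The NEX comparison asked what changes by E14.5 when Sip1 is removed from postmitotic neurons. Plcl1 was 3.65-fold higher on the arrays labelled mutant (log2 difference 1.87 ± 0.18 SE, limma adjusted p = 0.00378, n = 2 per label), the opposite of its direction in the Nestin experiment as labelled; with the Nestin labels exchanged it would be higher in both. S100a10 was 2.31-fold higher (1.21 ± 0.16, limma adjusted p = 0.0460), and D2hgdh, a mitochondrial dehydrogenase, 2.13-fold higher (1.09 ± 0.12, limma adjusted p = 0.00751). Usp21, a deubiquitinase, was 1.89-fold lower (-0.91 ± 0.10, adjusted p = 0.00727). These 3 genes lost their calls without NEX control 1 (S100a10 adjusted p = 0.383, D2hgdh 0.126, Usp21 0.104) and without NEX mutant 1 (0.246, 0.0526 and 0.0567), while Plcl1 kept its call without any single array. An unnamed probe (299021), given here after its value was seen, was also higher, but was above background on 1 of the 2 arrays labelled mutant and on neither labelled control.

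These 5 features, 4 higher and 1 lower, were all that passed among 28140 tested, while 712 had an unadjusted p under 0.05. Fgf9 gave -0.03 ± 0.28 and Sfrp1 -0.16 ± 0.12 (adjusted p = 1.00 for both). None of the 32 lists passed with camera, with an estimated correlation or with fry, and 5 had an unadjusted camera p under 0.05. Intermediate progenitor genes had a median of -0.10 and choroid plexus genes of 0.29 (camera adjusted p = 0.123 for both). Interneuron genes had a median of 0.05 (adjusted p = 0.299). NEX mutant 1 was the one NEX array with a high signal for the X-inactivation transcript Xist (log2 intensity 10.04 against 5.73 to 5.98 on the others). Its signal for the Y-linked gene Eif2s3y was low (6.19 against 9.08 to 9.52). By these transcripts it came from a female and the other NEX arrays from males, so sex was not balanced between the NEX labels. Without NEX mutant 1 the count was 10, without NEX mutant 2 it was 20, and without NEX control 2 it was 11. Without NEX mutant 1, NEX control 1 or NEX control 2, 6, 5 and 3 lists passed, and without NEX mutant 2 or Nestin control 2.2, 1 list did. Of features, none passed without the litter term (limma), and 2 did with replicate numbers as a block.

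The difference between both effects was tested directly, with stage, driver and experiment changing together. As labelled it passed for 61 features, 42 with a higher value in NEX and 19 with a lower one, and with the Nestin labels exchanged, a setting chosen after the data were seen, for 69. The widest as labelled was Plcl1 (NEX minus Nestin 4.24 ± 0.22 on the log2 scale, limma adjusted p = 7.00e-06), which gave -0.50 ± 0.22 (adjusted p = 0.585) with the labels exchanged. Wfdc2 (2.69 ± 0.22), Mfsd6 (2.42 ± 0.40), Helt (1.86 ± 0.20), Dmrta1 (1.77 ± 0.23) and Tmem229a (1.604 ± 0.13) followed on that side; of these Mfsd6 (0.05) and Helt (-0.26) did not pass with the labels exchanged. On the other side were Npy (-2.81 ± 0.31), Npas1 (-4.53 to -1.71 over the processing settings, its Nestin controls being near background), Rpp25 (-2.25 ± 0.29), Pnoc (-2.02 ± 0.24), Calb1 (-1.98 ± 0.34) and Gad1 (-1.58 ± 0.25). The interneuron list differed with an estimated correlation (median -0.50, adjusted p = 0.00378). The lists of radial glia, astroglia and microglia differed with the preset correlation but not with an estimated one (adjusted p = 0.0652 for each). Across features the Nestin and NEX differences correlated at 0.03, where features are not independent replicates. Without NEX control 2 the count of 61 was 24, and without Nestin control 2.1, Nestin mutant 2.2 or NEX mutant 1 it was 35, 31 and 36. Calb1 lost its call in 17 of 28 alternative settings, Mfsd6 in 16 and Gad1 in 12, among them most single arrays left out (without NEX mutant 1, adjusted p = 0.170, 0.183 and 0.170), and Dmrta1, Npas1 and Rpp25 without NEX control 2 (0.0569, 0.0758 and 0.0615).

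Nestin arrays labelled control (E18.5) were also set against NEX arrays labelled control (E14.5), where stage and experiment cannot be told apart, nor genotype if the Nestin labels are exchanged. Of 16 intermediate progenitor genes, 13 were lower at the later stage, and 14 adjusted over the list alone. Among them were the proneural genes Neurog1 (log2 difference -3.78 ± 0.13) and Neurog2 (-2.70 ± 0.14). All 28 cell cycle genes measured were lower, Top2a by -1.39 ± 0.09 and Cenpa by -1.80 ± 0.09. Embryonic globins were lower, Hbb-y by -6.33 ± 0.22 and Hba-x by -5.27 ± 0.21. Of 30 synaptic genes 20 were higher and 2 lower, with 21 higher adjusted over the list alone, including the GABA receptor subunit Gabra5 (3.17 ± 0.10) and the postsynaptic protein Nrgn (3.04 ± 0.15). Astroglial genes Clu (2.01 ± 0.13) and Hepacam (1.98 ± 0.11), the oligodendrocyte lineage gene Sox10 (1.79 ± 0.09) and the microglial gene C1qb (1.44 ± 0.12) were higher. Olig1 gave 2.27 and Tyrobp 1.201, but from litter 1 controls alone 0.64 and 0.60 and from litter 2 controls alone 3.901 and 1.80, and neither passed without the litter term (adjusted p = 0.264 and 0.0932). With the Nestin arrays labelled mutant in place of control, 11081 features passed and all 16 genes named here kept their direction, but C1qb gave 0.63 and Tyrobp 0.43. Meningeal genes Lum (-3.05 ± 0.14) and Dcn (-2.03 ± 0.13) were lower. Of the 32 lists, 10 passed camera in this comparison, 3 with an estimated correlation and 25 with fry. In all, 4770 features were higher and 6013 lower by limma with the litter term, which takes the distance between the litters out of the error, and the 10783 became 4140 without it. With litter 1 controls alone 13535 passed and with litter 2 controls alone 7219, settings chosen after the data were seen. Without NEX control 1 the count was 7085.

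**Figure D3:**
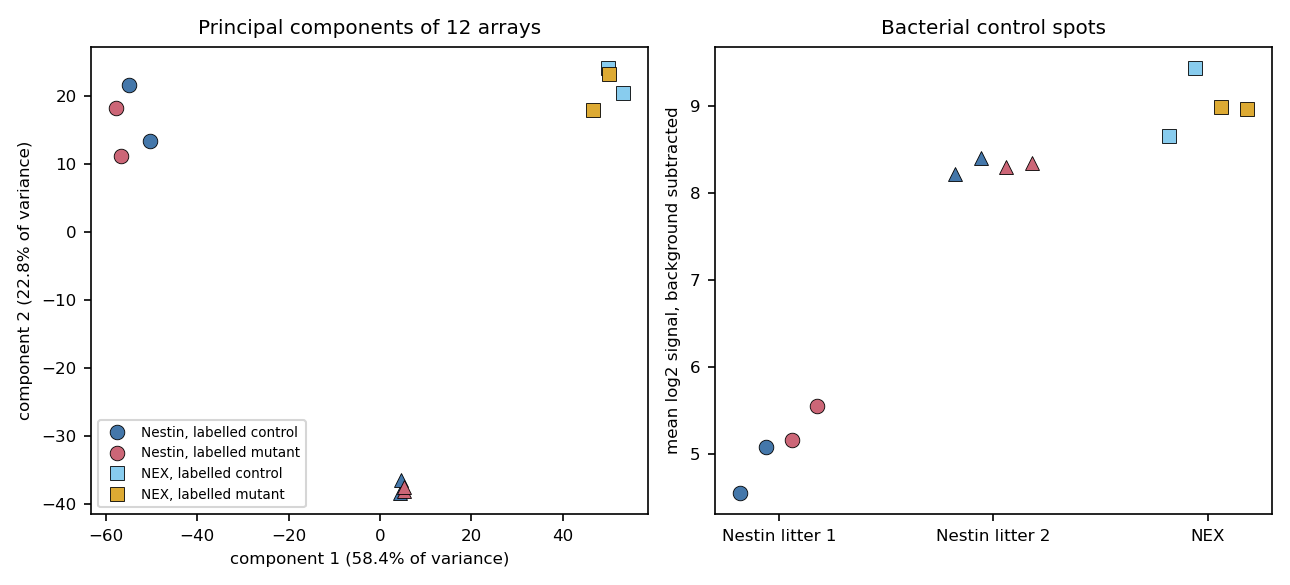
Left, principal components 1 and 2 of the 12 arrays (axes, scores; 58.4% and 22.8% of variance). Right, mean log2 background-subtracted signal of 6 bacterial control transcripts on each array (vertical axis) by litter or experiment (horizontal axis), with means of 5.09 on litter 1, 8.31 on litter 2 and 9.01 on NEX arrays.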

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

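The tests of explanations for the 3 patterns weighed here were chosen after the results were seen; those over other splits of the arrays and of the difference between experiments were chosen before the data were examined.

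The Zeb2 probes read higher, not lower, on the Nestin arrays labelled mutant. A candidate explanation is an exchange of the Nestin group labels, which predicts that genes known to rise on loss of Sip1 would appear to fall, and Fgf9 (log2 difference -1.34) and Sfrp1 both fell past the threshold. The NEX experiment, of another stage and driver, does not settle it: Plcl1, the 1 NEX call also called in Nestin, had the opposite sign there, while 57.8% of the Nestin calls shared their sign with NEX against 51.9% of all features, an excess not tested over dependent features, and the effects correlated at 0.03 across features. Epithelial genes that ZEB factors repress in other tissues also fell on the arrays labelled mutant, with 3 of 23 lower and none higher (camera adjusted p = 0.00456). An exchange would give this direction if they are repressed in cortex too, which was not tested. With an estimated correlation that list did not pass (camera adjusted p = 0.378). Another possible explanation is that both probes lie outside the deleted part. The second probe's difference of 0.53 cannot decide this because its place is not known here. No sample was reassigned, and a genuine rise in the mutant stays open and untested.

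Interneuron genes were higher while astroglial and microglial genes were lower on the Nestin arrays labelled mutant. For ventral forebrain tissue carried over in dissection, as the whole source, the prediction was that ganglionic eminence and striatum genes rise about as much. Their median lay below the interneuron median by 0.67, more than the 0.47 SD of their members. However, 5 of 18 rose adjusted over the list alone. Carried tissue need not raise both lists equally, so the medians cannot decide this. A lower share of the main cell type would raise markers of all other types, but the microglial median was -0.29. The processing batch of the litters is argued against by interneuron medians above 0 in both, the lower being 0.75. Carried-over ventral tissue stays open. So does, as a hypothesis, a change in interneuron number or in their gene expression, in either direction of the true genotype.

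The arrays of both Nestin litters lay far apart. The array lot, inferred from the array identifiers, does not account for this, since the SD of the litter difference across features was 0.487 within 1 such lot. Over all arrays it was 0.493. Whether the inferred grouping is the production lot is not given in the labels used here. A difference in age between the litters cannot be told apart from other sources: the litter difference correlated across features with the stage difference at 0.661 from litter 1 controls, -0.0227 from litter 2 controls and 0.408 from the mean of both, but the litters enter both sides, which pulls the first value up and the second down. Litter 2 lay nearer the NEX arrays (median r 0.966) than litter 1 did (0.935), which either age or a batch could give. A labelling or hybridisation batch may be a source, as bacterial control transcripts were dimmer on litter 1 than on litter 2 (log2 difference -3.23). Control RNA added at another amount could give this too, and median background-subtracted probe signal was alike in both (79.7 to 108.3 and 82.6 to 94.1 units). The mean also hides unequal gaps between the control transcripts. HISB read 6.02 to 7.44 on litter 1 and 8.49 to 8.70 on litter 2, and GND 3.09 to 4.32 and 8.02 to 8.28. Other measures separated the litters: local background was 112 to 115 units on litter 1 and 82 to 85 on litter 2. Probes above background were 77.3% to 79.4% and 82.9% to 84.3%. Negative control spots read 1.87 to 2.86 and 3.24 to 3.54 on the log2 scale. The source of these differences was not tested.

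Of the 34 splits of the 8 arrays that can be fitted with the litter term, 1, the labelled one, gave as many as 909 features. The highest other gave 1. Splits with uneven shares of the litters do not match the design, and every other split leaves the labelled difference in its error. The low counts therefore cannot exclude chance. The 18 splits with 2 arrays of each litter on each side, which match the design, are too few for a share under 0.05 (909 features against 1 in the highest other). The split that follows the litters, fitted without that term, gave 13875 features, a structure of the samples. For gene lists, 1 of 34 splits gave as many as the 11 called, but the highest other gave 10, so a count of lists from the preset correlation stands little above that of arbitrary splits.

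With the Nestin labels as given, the effects of both experiments differed, by the test of the difference itself, for Plcl1 (4.24), Wfdc2 (2.69), Mfsd6 (2.42), Helt (1.86), Dmrta1 (1.77), Tmem229a (1.604), Npy (-2.81), Npas1 (-2.32, from -4.53 to -1.71 over the processing settings), Rpp25 (-2.25), Pnoc (-2.02), Calb1 (-1.98) and Gad1 (-1.58), as log2 NEX minus Nestin; Calb1 lost this call in 17 of 28 alternative settings, Mfsd6 in 16 and Gad1 in 12. With the Nestin labels exchanged, Plcl1 would give -0.50, Mfsd6 0.05, Helt -0.26 and Rpp25 1.54, none past the threshold, and the other 8 genes would pass with the opposite sign. Gene lists differed for interneurons (camera adjusted p = 2.49e-15), microglia (4.74e-08), astroglia (6.28e-06), cell cycle (0.000360), radial glia (0.000367), ZEB-repressed epithelial genes (0.0140), ERK feedback (0.0147), meninges (0.0332), immediate early genes (0.0358) and synapse (0.0430), of which interneurons alone held with an estimated correlation. A lone array stood far from the other 3 of its label for Rpp21 (7.56 on Nestin control 1.2 against 9.20 to 9.41) and for Tac2 (6.77 on Nestin control 1.2 against 6.26 to 6.29). These are 2 of 62 groups tested, and chance flags about 1 in 20. Bacterial control transcripts, which stand outside the comparisons, averaged 5.09 on litter 1, 8.31 on litter 2 and 9.01 on NEX arrays, each above the negative control spots (at most 3.54).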

How the results depend on the processing

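The alternative settings were fixed before the data were examined; the stage test with controls of 1 litter and the exchange of the Nestin labels were added afterwards. Of 113 results for named genes past the threshold, none reversed under any alternative other than that exchange. Over 3428 values 2908 stayed past the threshold and 520 did not, most often without the litter term. The cause was not tested unless the setting itself gives it, as with fewer arrays. A lone NEX array left in a group was assumed to vary like the other groups, and spots near background limit what dim genes can show.

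The number of Nestin genes changed, 909, was 467 with plain background subtraction, 396 with the software's normalized intensity, 462 with the authors' value table, 178 with no replicate block (no litter term), 539 with the arrays of 1 genotype and litter averaged, 189 within litter 2 and 339 when at least 1.5-fold was asked for. The count within litter 2 was judged against a spread shared by all arrays. Leaving out 1 array gave 530 (without control 2.1) to 792. Zeb2 ran from 0.53 to 1.28 and passed the threshold in 10 of 32 settings. The Nestin lists of interneurons, astroglia, radial glia and microglia passed in all 33 alternatives (highest adjusted p = 0.00132, 0.0297, 0.0297 and 0.0407), while the number of Nestin lists fell from 11 to 4 with an estimated correlation.

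The NEX count of 5 was 10 with plain background subtraction, 11 with the authors' value table, 1 with probes above background on all 12 arrays, 0 without the litter block, 2 with the replicate number as a block, and 1 when the experiment was fitted alone. Leaving out 1 array gave 4 to 20 (without NEX mutant 2). Plcl1 lost its call in 1 of 29 settings, S100a10 in 18 of 29, D2hgdh in 7 of 26 and Usp21 in 9 of 28. Gene lists in NEX numbered 1 without the litter block, 1 with the experiment fitted alone and 7 with arrays averaged, and 0 to 6 (without NEX mutant 1) on leaving out 1 array. The NEX difference of Zeb2 was -0.0605 with its other probe and ran from -0.36 to 0.80 on leaving out 1 array, and that of Fgf9 from -0.46 to 0.40, so neither has a settled direction.

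The difference between both effects, 61 features, was 25 with plain background subtraction, 12 with the software's intensity, 23 with the authors' table, 8 without the litter block, 103 with the replicate number as a block, 100 with litter and array lot as blocks, and 150 with array weights. Leaving out 1 array gave 24 (without NEX control 2) to 72. Its lists numbered 1 with an estimated correlation, 3 with fry, and 5 to 12 on leaving out 1 array. The meninges list ran from adjusted p = 2.7e-07 to 0.851 (without NEX mutant 1) and is not a firm result. Fits of each experiment alone give no value for it. The stage count of 10783 was 4140 without the litter block and 7085 (without NEX control 1) to 11498 on leaving out 1 array.

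With the Nestin labels exchanged, every Nestin difference changes sign by construction. The difference between experiments then passed for 69 features and 12 lists. It reversed for Plcl1 (-0.50), Wfdc2 (-2.74), Helt (-0.26), Dmrta1 (-1.72), Tmem229a (-1.84), Npy (2.44), Rpp25 (1.54), Pnoc (2.12), Calb1 (2.16) and Gad1 (2.095). It also reversed for Npas1 (2.09), a value that is not exact because the Nestin arrays labelled control were near background for this gene. Its lists reversed for interneurons (adjusted p = 3.2e-20), astroglia (5.75e-07), microglia (2.98e-06), cell cycle (1.3e-05), immediate early genes (0.00735), radial glia (0.00756), ZEB-repressed epithelial genes (0.0314), and ERK feedback and meninges (0.373 for both).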

Other observations

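Cortical layer genes went both ways on the Nestin arrays labelled mutant. Of 22 deep-layer genes 3 rose and 2 fell: Crym rose by 1.06 ± 0.24 on the log2 scale and Bcl11b, a determinant of neurons projecting out of the cortex, by 1.02 ± 0.15, while Zfpm2 (-1.21 ± 0.14) and Tshz2 (-0.88 ± 0.14) fell. Of 19 upper-layer genes Inhba rose (0.61 ± 0.08) and Epha3 (-0.79 ± 0.14), Nectin3 (-0.62 ± 0.09) and Pou3f2 (-0.46 ± 0.11) fell. Neither list passed the set test (limma camera adjusted p = 0.571 and 0.267), and for the upper-layer list the median (0.03) and the direction of the test differed in sign.

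Among signalling genes, Rspo3, a Wnt agonist, was lower (-0.76 ± 0.09), as were the BMP ligands Bmp2 (-1.26 ± 0.31) and Bmp7 (-0.66 ± 0.13) and the receptor Fzd2 (-0.48 ± 0.08). The oligodendrocyte lineage genes Olig1 (-0.56 ± 0.09) and Olig2 (-0.42 ± 0.09) were lower, with 3 of 21 members past the test. Ganglionic eminence and striatum genes gave 1 member higher, Foxp1 (0.70 ± 0.10), and 1 lower, Penk (-0.74 ± 0.13), of 18. Crym, Pou3f2, Bmp2, Bmp7 and Olig2 lost their calls without Nestin control 2.2 (limma adjusted p = 0.101, 0.122, 0.124, 0.0660 and 0.0940). Bmp2 lost its call without any single Nestin array (0.0676 to 0.132), and the other genes lost theirs without several other single arrays. Over 31 alternative settings, Bmp2 lost its call in 23, Olig2 in 17, Pou3f2 in 16, Crym in 13 and Bmp7 in 11. No pericyte, erythroid or choroid plexus gene passed the test by limma.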
